A study of Homo sapiens with 15 samples.

How the data were processed

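Gene expression was measured in FACS-sorted human SCC-25 cells from mouse xenografts. RNA was amplified as whole-transcriptome cDNA, labelled with Cy3 and hybridised to one-colour Agilent arrays, per the labels' protocols. The scanner images were processed with Agilent Feature Extraction 10.7.3.1, and the deposited gProcessedSignal is an intensity after background subtraction and spatial detrending, with no scaling between arrays, per the file headers. The deposited mean and background signals are raw intensities, per the file headers. The authors' value table holds log2 values between 5.65 and 18.5 whose columns share the same quartiles, as between-array quantile normalization gives, with a column median of 7.10; how it was made is not given in the sources used here. Each of its 15 columns correlated best with the scanner values of its own array (lowest rank correlation 0.9965), so that its direction and the array of each column are known from the data. A rank correlation does not show the scale.

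Samples were grouped by the population named in their titles. Each array held 62976 spots, of which 58717 were no controls and represented 50599 probes. Spots marked as outliers were left out and no spot was saturated. Of the probes, 28170 were named through their accession in the RefSeq table, 2621 by symbol and 620 by synonym, and 19188 kept the name in the file. Log2 signals were reduced by the 75th percentile of the array, spots of a probe were averaged, and the 2 arrays of each set 8B population were averaged, because they are technical replicates (r between 0.991 and 0.993). Probes were kept where they were well above background in at least 4 of the 12 samples and had a value in all 12, and the brightest probe stood for a gene, which left 26697 genes. A probe that was not well above background on any array of a population has only a bound there. Its fold is given as at least the ratio of the brighter mean to the mean of the floor, where the floor of an array is the higher of its lowest signal among probes well above background and the probe's own signal. The same bound is given for a gene that was well above background in only some samples of the dimmer population.

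All 12 samples entered 1 linear model in limma 3.58.1 under R 4.3.3, with population and set as additive terms, 6 residual degrees of freedom and empirical Bayes moderation (2.51 prior degrees of freedom); tests were two-sided with a Benjamini-Hochberg threshold of 0.05. The set was a block because the series' design text says that the populations of a set were sorted from the same biological replicate. Deviations from the population means correlated between same-set samples of different populations with r from 0.13 to 0.41 (median 0.33, 12 pairs). For different sets r ran from -0.35 to 0.32 (median -0.13, 36 pairs). Deviations from a population mean sum to 0 over its sets, which by itself pulls the different-set values below 0. All pairs of set 8A with set 8B were positive, from 0.06 to 0.32. DID+ 8A correlated more with CD44n of set 8B (0.32) than with CD44n of its own set (0.26). So did DID- 8A (0.18 against 0.13). Whether sets 8A and 8B are as independent as the others was not tested. Whether a biological replicate was 1 animal is not given in the sources used here. Gene lists were tested with camera (preset correlation 0.01, and with the correlation estimated) and fry, with Benjamini-Hochberg adjustment over the 21 lists of a comparison. "Passed" refers to camera with the preset correlation unless another test is named. The lists covered fatty acid uptake, oxidation and synthesis, cell cycle, quiescence, basal and differentiating squamous epithelium, mesenchymal transition, hypoxia, oxidative phosphorylation, interferon, inflammation, immediate early genes, the unfolded protein response, stem cell markers, signalling targets, ribosomal proteins and 4 groups of other cells. Of the fibroblast and pericyte list 16 of 23 genes were measured in these cells, of the endothelial list 12 of 16, of the leukocyte list 15 of 24 and of the muscle, adipocyte and erythrocyte list 14 of 22; 1 fibroblast gene, THY1, stood in another list too. In 11 of the 63 list tests the mean, the median and the test differed in sign, none with an adjusted p under 0.05.

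The genes named were fixed by rule. For each comparison they were the 12 highest and 12 lowest log2 differences among genes past the threshold that have a gene symbol and moved the same way in 4 of 4 sets, or the 6 with the smallest unadjusted p in a direction where none passed. The 2 highest and 2 lowest members of each list by moderated statistic could also be named, with CD44 and CD36. Not every gene that the rule selects is named in the text. Design, lists, rule and alternatives were set before the data were examined. The alternatives were normexp background correction (offset 50), quantile normalization, median centring, the authors' values, no filter or a stricter filter on dim probes, the mean of a gene's probes, no set block, the slide as a covariate or alone, each technical replicate alone, the compared populations alone, array weights, and each set left out. A direction that changed counts as turned only where the value passed the threshold in one of the fits. For a list this is the direction of camera's test, which can differ from the sign of the list mean. The 15 arrays lay on 2 slides, each scanned in 1 run. Each slide held all 3 populations, but the layout was not balanced. DID+ and DID- lay on slides 1 and 2 in sets 8A and 9B and on slides 2 and 1 in set 10A. CD44n lay on slide 1 in sets 8A and 10A and on slide 2 in set 9B. Only set 8B was on both slides. Outside set 8B, each within-set difference between DID+ and DID- thus holds the slide difference, and a within-slide fit compares partly different sets. On data simulated for DID+ against DID- with the real spread of 26697 genes, the model recovered 56% of 50 genes changed by 1 log2 unit, 94% of 50 at 2, 98% of 50 at 3 and 96% of 50 at 4, with 8 false calls among 180.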

Results

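SCC-25, an established human oral squamous cell carcinoma line, was grown as an orthotopic xenograft in NSG mice, which lack most of the immune system, and tumour cells were sorted into 3 populations. The labels call these DID+, DID- and CD44. The array names give the first 2 as CD44p and the third as CD44n, and the third is called CD44n here; the labels do not define DID. Each population was taken from 4 biological replicates (sets 8A, 8B, 9B and 10A), so that n = 4 per population. RNA was measured on 15 one-colour Agilent arrays, since each population of set 8B was hybridised a second time, and those technical pairs were averaged to leave 12 samples. Between 64.9% and 72.5% of the spots of an array were well above background, and the 75th percentile of the processed signal lay between 371.9 and 567.0 intensity units. The share above background was higher in DID+ than in DID- samples by 2.35 percentage points (SD 1.71, in 4 of 4 sets) and than in CD44n samples by 3.04 (SD 3.33, in 4 of 4 sets). A total of 26697 genes was tested with limma. The number of arrays limits the precision: the median standard error of a log2 difference was 0.16. Values below are log2 signals relative to the 75th percentile of the array, and adjusted p-values are Benjamini-Hochberg values from limma unless a gene list is named. Probe positions are on hg19.

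The series title names CD36, a membrane receptor that takes up fatty acids, and CD44 was a marker of the sort. CD36 (probe on chromosome 7, 80302711 to 80303343) was 3.1-fold higher in DID+ than in DID- cells, with a log2 difference of 1.63 ± 0.28 (SE, adjusted p = 0.0362) and the same direction in 4 of 4 sets. Its signal was 1.14 ± 0.73 in DID+, -0.49 ± 1.51 in DID- and 0.58 ± 1.02 in CD44n (SD, n = 4). The differences of DID- (-1.06, adjusted p = 0.0714) and of DID+ (0.57, adjusted p = 0.629) from CD44n cells did not pass. CD44 (chromosome 11, 35253812 to 35253871) had a signal of 2.21 ± 0.14 in DID+, 2.21 ± 0.39 in DID- and 2.10 ± 0.36 in CD44n cells, and neither CD44p population differed from CD44n by more than its error (0.11 ± 0.13 for each, SE). CD36 did not pass between DID+ and DID- without the set block (adjusted p = 0.377), with the slide in the fit (1.57, adjusted p = 0.0563), within slide 1 (1.40, adjusted p = 0.626) or within slide 2 (1.58, adjusted p = 0.585). Nor did it pass without the filter on dim probes (adjusted p = 0.0709), with only the 2 populations in the fit (adjusted p = 0.145) or with any 1 set left out (1.20 to 1.82, adjusted p from 0.103 to 0.193), always with the same direction. The difference between DID- and CD44n passed with normexp background correction (adjusted p = 0.0164), the authors' processed values (0.0134), probes above background in all 12 samples (0.0397) and array weights (0.0464).

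**Figure D1:**
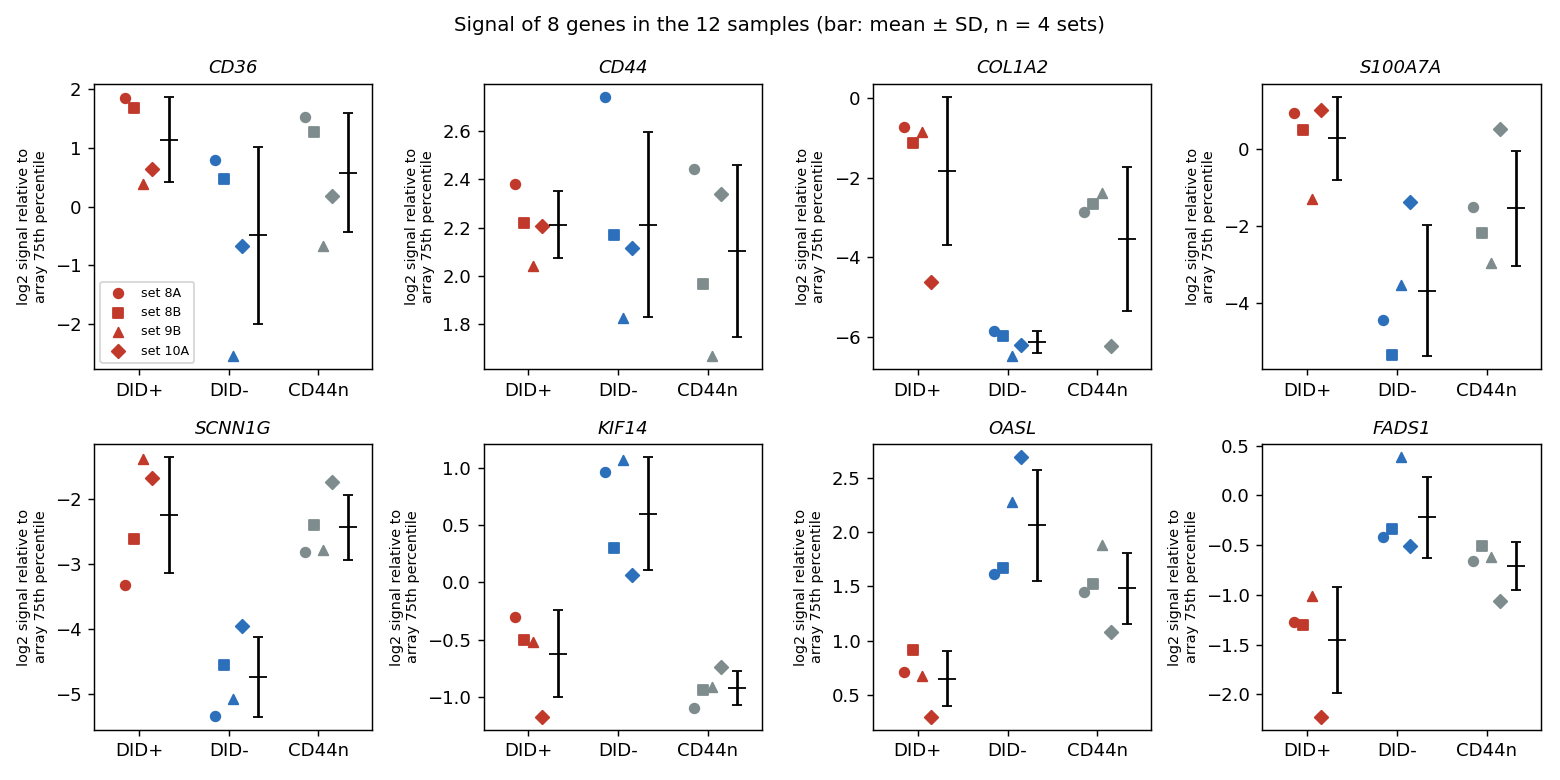
Signal of 8 genes in each of the 12 samples, as log2 relative to the 75th percentile of the array (vertical axes differ between panels); points are samples, symbols are sets, and the bars give the mean ± SD of 4 sets. CD36 is higher in DID+ than in DID- cells of every set, CD44 overlaps between populations, and COL1A2 lies near its floor in all 4 DID- samples.

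The first comparison asks how CD44p cells with DID differ from CD44p cells without it. DID+ cells had lower signals of cell division genes and higher signals of genes of squamous differentiation than DID- cells by camera's test of gene lists with a preset correlation (both adjusted p = 0.105 with an estimated correlation). In all, 207 genes were higher and 281 lower in DID+, of which 110 and 23 differed by at least 2-fold (3 of the 110 fell short of it with signals below the floor of an array raised to that floor). Median centring gave 228 higher and 1099 lower, 17.2% higher against 42.4%. Higher in DID+ were S100A7A (at least 12.8-fold, well above background in 2 of 4 DID- samples, adjusted p = 0.0311), S100P (6.57-fold, 2.72 ± 0.43, adjusted p = 0.0323) and S100A7 (5.02-fold, 2.33 ± 0.19, adjusted p = 0.0131), which encode calcium-binding proteins. C11orf96 had the smallest adjusted p (6.22-fold, 2.64 ± 0.16, adjusted p = 0.00307). The small mucin MUCL1 (7.46-fold), the proton pump subunit ATP6V0A4 (5.33-fold) and the metalloreductase STEAP4 (4.82-fold) were also higher. Some genes were well above background in only part of the DID- samples and have a bound: the lipase family member PNLIPRP3 (at least 6.42-fold, 3 of 4 samples), the cytidine deaminase APOBEC3A (at least 3.99-fold, 2 of 4) and the sodium channel subunit SCNN1G (at least 3.87-fold, 1 of 4). C5orf46 was at least 2.88-fold higher, with 0 of 4. COL1A2, a chain of type I collagen (chromosome 7, 94058643 to 94058702), was not well above background on any DID- array and was at least 5.80-fold higher in DID+ (adjusted p = 0.0311). It measured -1.83 ± 1.87 in DID+, where it was well above background in 3 of 4 samples, and -3.54 ± 1.81 in CD44n (SD). Single sets moved some of these values: without set 9B, PNLIPRP3 was at least 4.25-fold higher (adjusted p = 0.0492) and APOBEC3A did not pass (adjusted p = 0.115), nor did S100A7A without set 8B (adjusted p = 0.193). No gene at all passed without set 8A or without set 8B. COL1A2 was at least 4.58-fold, 4.92-fold and 4.55-fold higher without sets 8A, 8B and 9B. Without set 10A COL1A2 was at least 11-fold higher (adjusted p = 0.00391), and without the filter on dim probes it did not pass (adjusted p = 0.065).

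The genes lower in DID+ cells included the interferon-induced OASL (2.66-fold, -1.41 ± 0.27, adjusted p = 0.0449) and the dynamin DNM3 (2.49-fold). The replication factors DTL (2.35-fold lower), CLSPN (2.35-fold) and PCLAF (2.28-fold), the mitotic kinase MELK (2.41-fold) and the mitotic kinesin KIF14 (2.33-fold) were lower too. FADS1, a fatty acid desaturase, was 2.35-fold lower (-1.23 ± 0.17, adjusted p = 0.0311). Well above background in only 2 or 3 of 4 DID+ samples, COCH (at least 2.61-fold, 2 of 4), the signalling adaptor TRAF5 (at least 2.36-fold, 2 of 4) and PEG10 (at least 2.33-fold, 3 of 4) were also lower. Those without a bound moved the same way in 4 of 4 sets, as the rule for naming them requires.

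Of 40 cell cycle genes, 20 fell in DID+ and none rose (36 fell when adjusted over the list alone). The mean over the list was -0.71 ± 0.22 (SD of 4 sets), with MCM6 2.0-fold and MCM2 1.87-fold lower, both parts of the replicative helicase. The list passed camera's test with a preset correlation (adjusted p = 1.19e-27), and gave an adjusted p = 0.105 with an estimated correlation. Its mean was -0.52 within slide 1, -0.89 within slide 2 and -0.76 with the slide in the fit. Of 43 squamous differentiation genes, 8 rose and none fell (23 rose when adjusted over the list alone). The list mean was 0.78 ± 0.55 (adjusted p = 6.32e-13, and adjusted p = 0.105 with an estimated correlation). S100A7 and filaggrin, FLG (1.93, adjusted p = 0.0311), a protein of the cornified layer, led this list. Its mean was 0.60 within slide 1, 0.81 within slide 2 and 0.71 with the slide in the fit. It was smallest in set 10A (0.36), where DID+ cells also had the lowest COL1A2 signal (-4.62) and the cell cycle list its largest shift (-0.99). A link between these values cannot be drawn from 1 set. The squamous mean was largest in set 9B (1.58), where the DID- list mean was the lowest (1.29), and without that set it was 0.51 (adjusted p = 1.54e-10). The basal epithelium list was lower (-0.28 ± 0.15, adjusted p = 1.54e-06, and adjusted p = 0.105 with an estimated correlation), and 2 of its 22 genes fell, the integrin ITGA6 (-0.57) and the plakin DST (-0.66). When adjusted over the list alone 8 fell. The mean was -0.18 within slide 1 and -0.35 within slide 2. Of 21 cell cycle inhibitor and quiescence genes, only BHLHE40 rose (1.02, adjusted p = 0.0311), with 8 higher and 1 lower when adjusted over the list alone and a list mean of 0.31 (adjusted p = 0.00251, and adjusted p = 0.325 with an estimated correlation). It was 0.22 within slide 1, where it did not pass (adjusted p = 0.0584), and 0.33 within slide 2. Beside these groups, the immediate early and heat shock genes, which respond to handling, were higher in DID+ (0.44 ± 0.38, adjusted p = 0.000463, and adjusted p = 0.325 with an estimated correlation). Of those 30 genes EGR2 (1.33) and IER3 (1.02) rose, and 13 were higher and 3 lower when adjusted over the list alone.

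The lipid lists moved in different directions. Of 31 genes of fatty acid uptake and storage, CD36 and DGAT2, which makes triglycerides (1.22, adjusted p = 0.0311), rose and none fell, and 7 were higher and 3 lower when adjusted over the list alone. The list mean was 0.24 ± 0.07 (adjusted p = 0.0265, and adjusted p = 0.105 with an estimated correlation), 0.23 within slide 1 (adjusted p = 0.169) and 0.20 within slide 2 (0.101), which did not pass, as without set 8A (0.068), and 0.14 with median centring. No gene of the 27 in fatty acid oxidation passed, 6 were lower when adjusted over the list alone, and the list lay lower (-0.15 ± 0.09, adjusted p = 0.00607, and adjusted p = 0.105 with an estimated correlation), with -0.09 within slide 1, -0.18 within slide 2 (adjusted p = 0.0687) and -0.25 with median centring. ACADM, a mitochondrial dehydrogenase, stood at -0.49 (adjusted p = 0.0691). Of 30 genes of fatty acid and cholesterol synthesis, FADS1 was among those that fell and SC5D, an enzyme of sterol synthesis, rose (0.80, adjusted p = 0.0311). Of the list 5 were lower and 1 higher when adjusted over the list alone. That list had a mean of -0.25 ± 0.23 (adjusted p = 0.00067, and adjusted p = 0.325 with an estimated correlation), but the mean was 0.07 within slide 1 and -0.47 within slide 2, and -0.12 with array weights (adjusted p = 0.0564). No single gene of the 40 in oxidative phosphorylation passed, over all genes or adjusted over the list alone, though 39 had a negative log2 difference and the list mean was -0.23 ± 0.02 (adjusted p = 3.58e-10, and adjusted p = 0.097 with an estimated correlation). It was -0.15 within slide 1 and -0.29 within slide 2.

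Among 36 interferon response genes, 3 fell in DID+ cells (12 when adjusted over the list alone), including OASL and ISG15 (-1.02, adjusted p = 0.0311). The list mean was -0.46 ± 0.33 (adjusted p = 3.58e-10, and adjusted p = 0.209 with an estimated correlation), with -0.26 within slide 1 and -0.57 within slide 2. Of 28 inflammatory genes, the iron-binding lipocalin LCN2 rose (1.73, adjusted p = 0.0384), with 5 higher and 1 lower when adjusted over the list alone. Its mean was 0.39 (adjusted p = 0.00659, and adjusted p = 0.325 with an estimated correlation), and it did not pass within slide 1 (0.34, adjusted p = 0.169), within slide 2 (0.34, adjusted p = 0.143) or without the set block (adjusted p = 0.0617). The mean was 0.22 with the authors' processed values and 0.24 with normexp background correction. Of 29 genes of the unfolded protein response and ATF4, 3 fell, among them the amino acid transporter SLC7A5 (-0.73, adjusted p = 0.0311) and the serine synthesis enzyme PSAT1 (-0.86, adjusted p = 0.032). The mean of the list was -0.14 (adjusted p = 0.0358, and adjusted p = 0.209 with an estimated correlation), and 9 were lower and 4 higher when adjusted over the list alone. It passed in 13 of 19 settings and was -0.05 within slide 1 (adjusted p = 0.169) and -0.20 within slide 2 (0.109). It did not pass without set 8A (adjusted p = 0.169), with the slide in the fit (0.0699), with quantile normalization (0.084) or with probes above background in all 12 samples (0.102), and was -0.23 with median centring. The epithelial to mesenchymal list (-0.09, adjusted p = 0.0365, and adjusted p = 0.404 with an estimated correlation) had no gene past the threshold and 5 lower ones when adjusted over the list alone. It passed in only 9 of 19 settings, and its mean was 0.11 without the filter on dim probes (adjusted p = 0.141), -0.04 within slide 1 (0.255), -0.09 within slide 2 (0.134), -0.06 with the slide in the fit (0.128) and -0.19 with median centring (0.0642). It stood at -0.03 without set 9B (adjusted p = 0.154), -0.08 without 8A (adjusted p = 0.068) and -0.16 without 10A (adjusted p = 0.015). The ribosomal protein list (-0.06, adjusted p = 0.0386, and adjusted p = 0.66 with an estimated correlation) had none by either count. It passed in 9 of 19 settings and stood at -0.02 without 8A (adjusted p = 0.319) or 8B (0.354), -0.06 without 10A (0.0657), -0.12 without 9B (0.00026), -0.15 with median centring and -0.10 with array weights. The leukocyte list was higher (0.44, adjusted p = 0.00385, and adjusted p = 0.105 with an estimated correlation). Of its 15 measured genes S100A9 (2.00) and S100A8 (1.55, both adjusted p = 0.0311) were the only 2 that rose by either count, and the list mean of 0.28 within slide 1 did not pass (adjusted p = 0.169; 0.58 within slide 2). Squamous epithelium also makes both proteins. The fibroblast and pericyte list did not pass (mean 0.49, adjusted p = 0.322), while its members COL1A2 and COL1A1 (1.25, adjusted p = 0.0323) rose and COL5A2 fell (-0.74, adjusted p = 0.0457), the same 3 when adjusted over the list alone. That mean counts COL1A2 with its DID- signals below the floor, and the list median was 0.17. Members such as COL3A1 and COL6A3 had been left out by the filter on dim probes. The fibroblast list passed in 0 of 19 settings, which include the fit without that filter. The lists of hypoxia (adjusted p = 0.517), stem cell markers (0.56), Wnt, Notch and TGF-beta targets (0.411), endothelium (0.569) and muscle, adipocyte and erythrocyte genes (0.119) did not pass. In these, KDM3A (0.52) and SOX9 (0.74) rose and DKK3 fell (-0.88). The list counts past the threshold were 15 of 21, against 8 within slide 1, 9 within slide 2 and 0 with estimated correlations. Of the 15, 11 also passed fry, which does not compare a list with other genes; fatty acid and cholesterol synthesis (adjusted p = 0.114), epithelial to mesenchymal (0.144), inflammatory (0.0846) and ribosomal protein genes (0.393) did not.

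The gene count of this comparison depended on the model. It was 488 with the sets as a block, 5 without the block, 145 with the slide as a covariate, 2 within slide 1 and 0 within slide 2, 3 without the filter on dim probes, and 0 to 4 when any 1 set was left out. All 488 genes kept their sign in each of these fits. Each of them had the same direction in 4 of 4 sets, so that leaving out a set or the block could not turn any.

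The second comparison sets CD44p cells without DID against CD44n cells. DID- cells had higher signals of cell division genes and lower signals of squamous differentiation and immediate early genes by camera's test with a preset correlation (adjusted p = 0.104, 0.104 and 0.165 with an estimated correlation). In all, 586 genes were higher and 342 lower in DID-, of which 81 and 153 differed by at least 2-fold (66 and 146 with signals below the floor raised to it). Median centring gave 1010 higher and 295 lower, 77.4% higher against 63.1%. The chemokine CCL5 (at least 10.0-fold, adjusted p = 0.027) and PADI3 (at least 2.73-fold), an enzyme that converts arginine in proteins to citrulline, were higher, each well above background in 3 of 4 CD44n samples. ZNF22 was not well above background in CD44n and was at least 1.81-fold higher (adjusted p = 0.0398). Well above background in 1 of 4 CD44n samples, DNM3 (at least 2.82-fold), GAREM2 (at least 1.97-fold), LHFPL6 (at least 1.92-fold), PDX1 (at least 1.78-fold) and EMILIN2 (at least 1.64-fold) were higher too, as were the mitotic genes ASPM (3.01-fold, 1.59 ± 0.20, adjusted p = 0.0223), TTK (2.93-fold), CENPA (2.93-fold) and KIF14 (2.87-fold). Lower in DID- were S100P (8.98-fold, -3.17 ± 0.43, adjusted p = 0.0224) and C11orf96 (7.10-fold, -2.83 ± 0.16, adjusted p = 0.00172). MSMB (5.89-fold), the cornified envelope protein CNFN (5.61-fold, adjusted p = 0.0113), the epidermal protease ASPRV1 (5.59-fold, adjusted p = 0.00727) and the immediate early factor NR4A1 (4.84-fold) were lower as well. Bounds hold for A2ML1, a protease inhibitor (at least 4.84-fold, above background in 3 of 4 DID- samples), ENDOU (at least 4.33-fold, 3 of 4), CYP4B1 (at least 4.36-fold, 2 of 4) and APOBEC3A (at least 3.33-fold, 2 of 4). SCNN1G (at least 3.41-fold) and PIGR, the receptor that carries immunoglobulins across epithelia (at least 3.28-fold, adjusted p = 0.0387), were above background in 1 of 4. Those without a bound moved the same way in 4 of 4 sets, as the rule for naming them requires. Without set 9B the decreases were at least 1.87-fold for PIGR (adjusted p = 0.0854) and 3.80-fold for MSMB (0.0643), CYP4B1 (0.0921) and APOBEC3A (0.0773) did not pass, and CCL5 was at least 15.5-fold higher (0.025). PIGR was at least 5.25-fold lower without set 8A. No gene at all passed without set 8A or without set 8B.

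Of 40 cell cycle genes 27 rose in DID- and none fell (37 when adjusted over the list alone), including TYMS (1.14) and CCNA2 (1.15), and the list mean was 0.77 ± 0.16 (adjusted p = 4.21e-27, and adjusted p = 0.104 with an estimated correlation). It was 0.70 within slide 1 and 0.81 within slide 2. Of 43 squamous differentiation genes 16 fell and none rose (34 when adjusted over the list alone), led by CNFN (-2.49) and the transglutaminase TGM1 (-1.41). The list mean was -1.05 ± 0.27 (adjusted p = 1.15e-20, and adjusted p = 0.104 with an estimated correlation), -0.95 within slide 1, -1.0 within slide 2 and -0.98 with the slide in the fit. Of 22 basal genes 5 rose (12 when adjusted over the list alone), including ITGA6 (0.70) and PDPN (0.82), and the list mean was 0.39 ± 0.06 (adjusted p = 2.67e-07, and adjusted p = 0.104 with an estimated correlation), 0.32 within slide 1 and 0.38 within slide 2. Of 30 epithelial to mesenchymal genes 7 rose and 1 fell (9 and 1 when adjusted over the list alone), with the integrin ITGAV at 0.93 and SNAI1 at -0.69, and a list mean of 0.35 (adjusted p = 3e-05, and adjusted p = 0.165 with an estimated correlation). Of 21 cell cycle inhibitor and quiescence genes, 5 fell, with BTG2 at -1.44 and BHLHE40 at -0.91, and GAS1 rose (0.79). When adjusted over the list alone 8 were lower and 3 higher, and the list mean was -0.32 (adjusted p = 0.0136, and adjusted p = 0.425 with an estimated correlation), or -0.20 without set 9B (adjusted p = 0.0876). It was -0.18 within slide 1 (adjusted p = 0.193), -0.38 within slide 2 and -0.22 with array weights (adjusted p = 0.123). Beside these groups, 12 of the 30 immediate early and heat shock genes fell (18 when adjusted over the list alone, with 2 higher), led by IER3 (-1.54) and KLF6 (-0.96). The list mean was -0.72 ± 0.32 (adjusted p = 1.2e-07, and adjusted p = 0.165 with an estimated correlation), -0.60 within slide 1 and -0.81 within slide 2.

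Of 31 fatty acid uptake and storage genes, ABHD5, an activator of fat hydrolysis, fell (-0.72, adjusted p = 0.0383), while the fatty acid activating genes ACSL4 (0.83) and SLC27A3 (0.52) rose. When adjusted over the list alone 5 were lower and 3 higher, and the list mean was -0.21 ± 0.10 (adjusted p = 0.00783, and adjusted p = 0.104 with an estimated correlation). At -0.20 in each slide alone it did not pass (adjusted p = 0.0686 and 0.0602). Of 27 fatty acid oxidation genes 3 rose, among them ACADM (0.64, adjusted p = 0.0315) and HADHB (0.59, adjusted p = 0.0333). When adjusted over the list alone 6 were higher and 1 lower, and the list mean was 0.17 ± 0.07 (adjusted p = 0.00933, and adjusted p = 0.104 with an estimated correlation), 0.18 within slide 1 and 0.13 within slide 2 (adjusted p = 0.0659). The oxidative phosphorylation list was higher (0.16 ± 0.06, adjusted p = 3e-05, and adjusted p = 0.104 with an estimated correlation), with NDUFS1 (0.70) as the only 1 of 40 genes that rose, and 2 when adjusted over the list alone. The interferon list was higher (0.20, adjusted p = 0.0123, and adjusted p = 0.552 with an estimated correlation) with no gene past the threshold by either count. Of 28 inflammatory genes CXCL8 (at least 3.85-fold, above background in 2 of 4 DID- samples), LCN2 (-1.91) and 2 others fell while CCL5 rose. When adjusted over the list alone 8 were lower and 1 higher, and the list mean was -0.46 (adjusted p = 0.00463, and adjusted p = 0.39 with an estimated correlation), with -0.14 within slide 1, where it did not pass (adjusted p = 0.762), -0.81 within slide 2 and -0.23 without set 9B (adjusted p = 0.0373). The leukocyte list was lower (-0.33, adjusted p = 0.0316, and adjusted p = 0.165 with an estimated correlation), with S100A9 (-1.79) and S100A8 (-1.24) as its only genes past the threshold; 3 were lower and 1 higher when adjusted over the list alone. It did not pass without set 8B (adjusted p = 0.143) or 9B (0.104), with the mean of a gene's probes (0.0827) or within slide 1 (-0.17, adjusted p = 0.342), and was -0.52 within slide 2. The lists of fibroblasts and pericytes (adjusted p = 0.381), endothelium (0.381), muscle, adipocytes and erythrocytes (0.152), fatty acid and cholesterol synthesis (0.34) and ribosomal proteins (0.778) did not pass. The lists of hypoxia (0.402), the unfolded protein response (0.481), stem cell markers (0.205) and Wnt, Notch and TGF-beta targets (0.381) did not pass either, and had members that moved both ways. Among these, PFKFB4 (0.93), SLC7A5 (0.58), ITGB1 (0.99), DKK3 (0.90) and TGFBI (0.78) rose, while EGLN3 (-1.37), DNAJB9 (-0.65), SOX9 (-0.74), ID1 (-1.07) and the Notch target HES5 (-1.06) fell. Of the fibroblast list only COL5A2 rose (0.93, adjusted p = 0.0251). COL1A2, not well above background on any DID- array, was at least 1.78-fold lower there without passing (adjusted p = 0.0619). Of the 12 lists past camera's threshold 11 also passed fry, and the interferon list did not (adjusted p = 0.288).

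The count of 928 genes was 27 without the set block, 629 with the slide as a covariate, 2 within slide 1, 0 within slide 2, 76 without the filter on dim probes and 0 to 6 when any 1 set was left out. Within slide 1 a total of 927 of the genes could be tested, and the genes kept their sign in each of these fits.

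**Figure D2:**
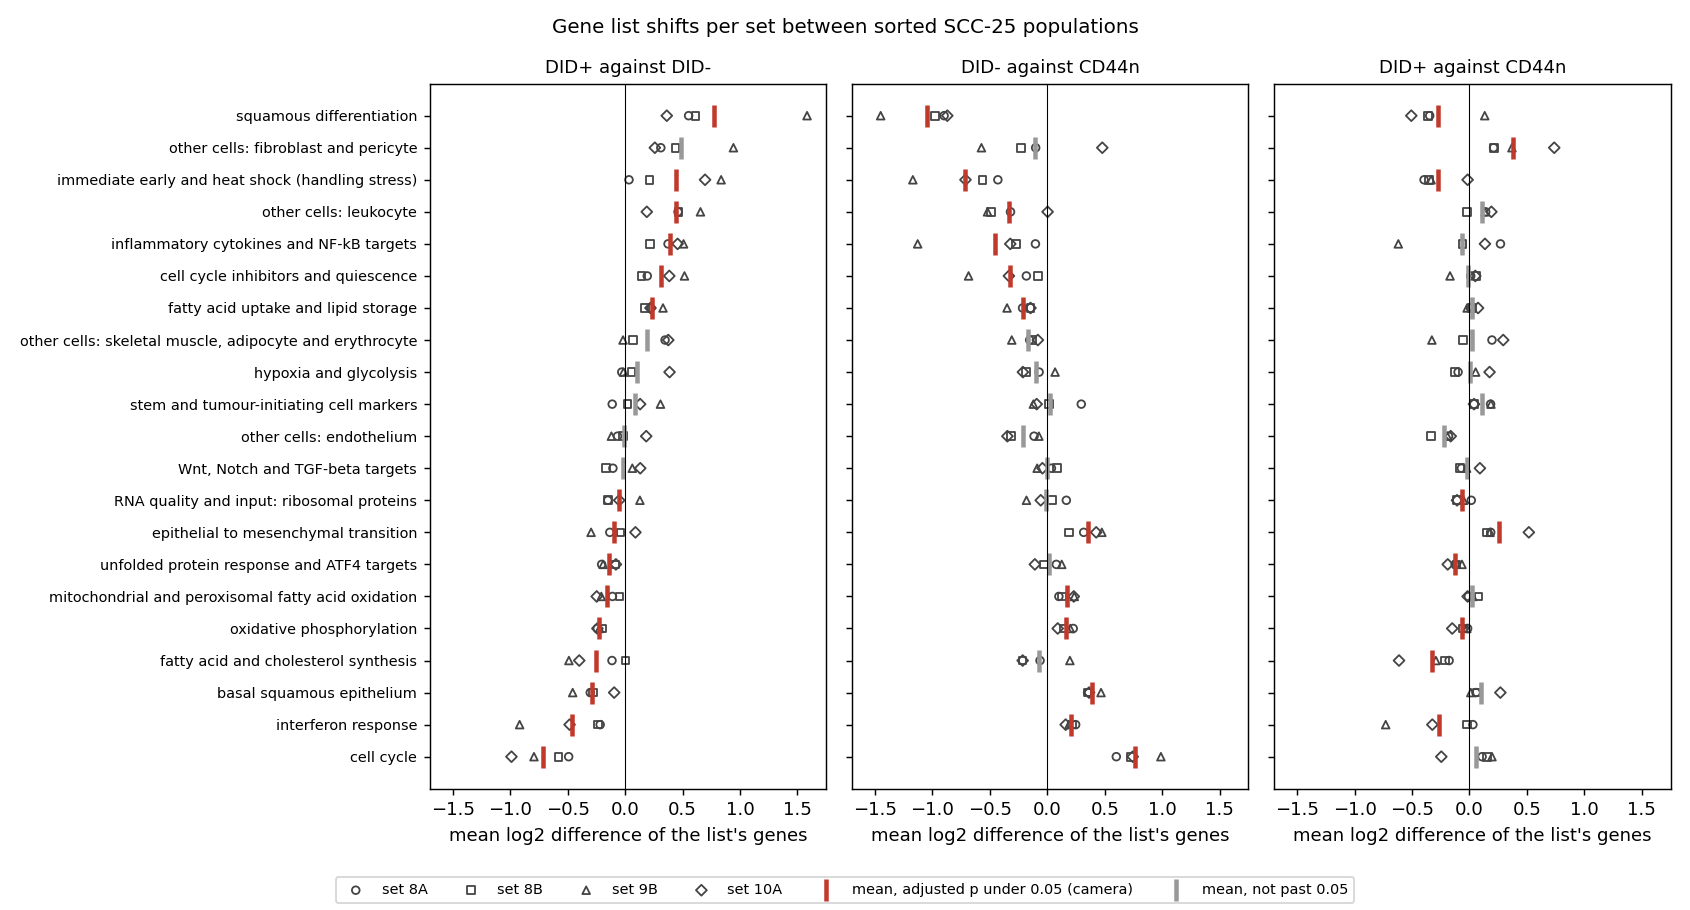
Mean log2 difference of each of 21 gene lists (rows) in the 3 comparisons (panels); open symbols are the 4 sets, and vertical bars are their means, red where camera's adjusted p with the preset correlation was under 0.05. The cell cycle list lies below 0 in all 4 sets for DID+ against DID- (mean -0.71) and above 0 in all 4 for DID- against CD44n (mean 0.77), while the squamous differentiation list shows the opposite signs (0.78 and -1.05).

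The remaining comparison sets DID+ against CD44n cells. No gene passed limma's adjusted threshold, and the smallest adjusted p was 0.0651. At an unadjusted p under 0.05 there were 2267 genes, where chance would give 1335. The genes with the smallest unadjusted p, none past the threshold, were BBS12, ZSCAN4 (at least 3.20-fold, above background in 2 of 4 CD44n samples), ENTPD7, COL13A1, S100A7 (1.28 ± 0.19) and PICART1 on the higher side. BBS12 and PICART1 were not well above background in CD44n, so that only a bound can be given, at least 1.34-fold and at least 1.57-fold. COL13A1 was well above background in 0 of 4 CD44n and 2 of 4 DID+ samples. Its bound of 0.893-fold does not show a rise. On the lower side they were ASPRV1 (-2.22 ± 0.20), THEM5 (-1.14 ± 0.14), the neuropeptide precursor NTS (-1.61 ± 0.22), FAM222A, the sterol sensor INSIG1 (-0.90 ± 0.14) and the epithelial transcription factor FOXN1 (-0.83 ± 0.13). Array weights gave 3 genes, the authors' processed values 3, normexp background correction 4 and the fit within slide 1 another 3.

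As groups, 9 of the 21 lists passed camera's test in this comparison, each without a single gene past the threshold over all genes, and none passed fry (smallest adjusted p = 0.174). The fatty acid and cholesterol synthesis list was lower in DID+ in 4 of 4 sets (-0.32 ± 0.20, adjusted p = 4.43e-09, and adjusted p = 0.351 with an estimated correlation), with 8 of 30 genes lower when adjusted over the list alone, and it was -0.18 within slide 1 and -0.48 within slide 2. The interferon list (-0.26 ± 0.35, adjusted p = 1.62e-07), the squamous differentiation list (-0.27 ± 0.28, adjusted p = 5.73e-05), the immediate early list (-0.27 ± 0.17, adjusted p = 5.73e-05), the unfolded protein response (-0.12 ± 0.05, adjusted p = 0.00808), oxidative phosphorylation (-0.06 ± 0.06, adjusted p = 0.0249) and ribosomal proteins (-0.06 ± 0.06, adjusted p = 0.0334) were lower. For the first 5 of these the estimated correlation gave an adjusted p = 0.351, and for ribosomal proteins an adjusted p = 0.918. The interferon mean was -0.08 within slide 1, where it did not pass (adjusted p = 0.0784), -0.41 within slide 2 and -0.16 with array weights. Within slide 2 the squamous list (-0.19, adjusted p = 0.158) and the unfolded protein response (-0.14, adjusted p = 0.125) did not pass, with -0.35 and -0.11 within slide 1, and the squamous mean was -0.17 with probes above background in all 12 samples. Oxidative phosphorylation passed in 10 of 19 settings (-0.04 within slide 1, -0.10 within slide 2 and with median centring, -0.02 with the authors' values or quantile normalization) and ribosomal proteins in 7 of 19, with means from -0.10 to 0.01. Adjusted over the list alone, 1 interferon gene and 2 squamous genes were lower, 2 squamous genes and 1 immediate early gene were higher, and the other 3 lists had none. The epithelial to mesenchymal list (0.26 ± 0.17, adjusted p = 0.00073) and the fibroblast and pericyte list (0.38 ± 0.25, adjusted p = 0.00337) were higher, both with an adjusted p = 0.351 with an estimated correlation. They held 2 and 1 higher genes when adjusted over the list alone; the decorin gene DCN stood at 1.20 and COL1A1 at 0.69, and the fibroblast mean was 0.55 within slide 1 and 0.04 within slide 2 (adjusted p = 0.893). Without the filter on dim probes the means were 0.42 and 0.60, and the epithelial to mesenchymal mean was 0.17 with probes above background in all 12 samples and the fibroblast mean 0.24 with normexp. Without set 10A the epithelial to mesenchymal mean was 0.17 (adjusted p = 0.0274), that of oxidative phosphorylation -0.03 (0.298), and the fibroblast (0.0591) and ribosomal (0.211) lists did not pass. Without set 9B the interferon mean was -0.10 (adjusted p = 0.00354). The oxidative phosphorylation (adjusted p = 0.0679) and ribosomal (0.176) lists did not pass without set 8B, nor the unfolded protein response without 8A (0.0727). The cell cycle list did not pass (0.05 ± 0.20, adjusted p = 0.455), and neither did fatty acid uptake (adjusted p = 0.885), fatty acid oxidation (0.885), quiescence (0.915), basal epithelium (0.139), hypoxia (0.885), inflammation (0.487), stem cell markers (0.315), Wnt, Notch and TGF-beta targets (0.885), endothelium (0.885), leukocytes (0.315) or muscle, adipocytes and erythrocytes (0.971).

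DID+ and CD44n cells were then set side by side through their differences from DID- cells, which share the DID- samples. Of the 207 genes higher in DID+ than in DID- and the 342 higher in CD44n than in DID-, 106 were the same genes, where independent lists would share 2.65 and the most extreme genes of unchanged populations, in lists of these sizes, shared 33.4 on average over 100 simulations. Of the 281 and 586 lower genes, 183 were shared, against 6.17 for independent lists and 61.4 in the simulations, and none was called in opposite directions. The simulated value leaves out the effects and the other leaves out the shared samples. Across genes, which are not independent replicates, the differences correlated with r = 0.72, and unchanged populations against the same DID- samples gave a simulated r of 0.50. The covariance was 0.106 against a simulated 0.026. With the sets split so that each difference used other DID- samples, r was 0.28 to 0.41 over 6 splits, and the median covariance was 0.078.

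**Figure D3:**
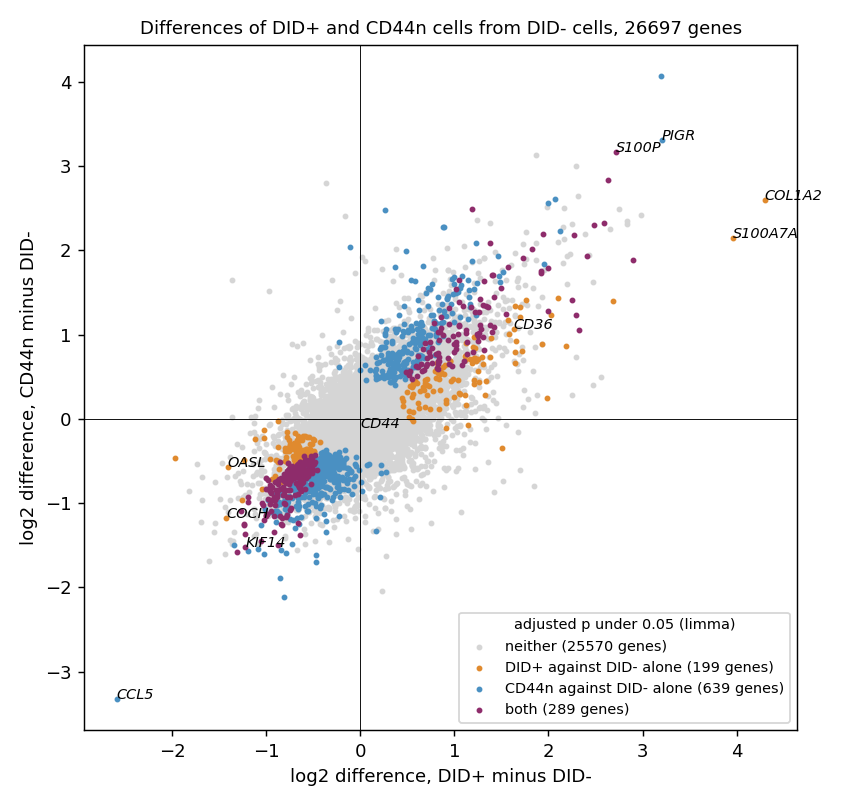
Log2 difference of DID+ from DID- cells (horizontal) against that of CD44n from DID- cells (vertical) for 26697 genes; colours mark the genes with an adjusted p under 0.05 in 1, both or neither comparison. The 289 genes called in both comparisons lie where both differences have the same sign, and part of the overall slope comes from the DID- samples that both axes share.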

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

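The tests of the slides and of fibroblast RNA on the collagens were chosen after the result was seen. Each list mean, each named gene and the share of probes above background was checked for a sample far from the 3 others of its population. Of 363 groups of 4 samples 30 held such a sample, where chance alone would give about 18.1. All values are log2 signals relative to the 75th percentile of the array; those below the floor of their array, such as -5.84 for ZNF22, have no order among each other.

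Genes of the fibroblast list placed set 10A apart. COL1A2 measured -4.62 in DID+ cells of set 10A, against -1.12 in the nearest other set, and -6.23 in CD44n cells of set 10A, against -2.85. COL1A1 measured -2.49 in CD44n cells of set 10A (nearest -0.84), COL5A2 -2.33 in DID+ cells of set 10A (nearest -1.35), and the mean of the fibroblast and pericyte list -0.47 in CD44n cells of set 10A (nearest 0.32). In set 8B, which was on both slides, COL1A2 measured -1.04 and -1.2 in DID+ cells and was not above background in DID- cells on either.

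The higher COL1A2 of DID+ cells was weighed as a slide effect and as RNA of fibroblasts carried through the sort. With DID- arrays set to their floor, the log2 difference was at least 3.4789 (SE 0.0939) within slide 1 and 1.4637 (SE 1.712) within slide 2. Slide 1 held DID+ arrays of sets 8A, 8B and 9B and DID- arrays of sets 8B and 10A, so that partly different sets are compared. Its SE takes DID- at the floor and leaves out their spread below it. The bound within slide 2 is smaller than its SE and decides nothing. A difference between slides adds nothing within one. Slide 1, where set 8B held both populations, thus argues against the slides as the whole source. Of the 22 other fibroblast list genes, 2 (COL3A1 and COL6A3) were among the 100 genes with the largest DID+ excess when dim probes were included. By their number 0.06 would be expected. At least 3 was set as the bound for carried-over cells, after the values were seen, and 2 falls short of it. That outcome hangs on the list: POSTN (rank 7) and SPARC (rank 9), which are outside it, were also among the 100. In a xenograft stromal cells come from the mouse, and the sort on CD44 need not remove them. How far mouse transcripts bind these human probes was not tested, so that even a count of 0 would not have excluded carried-over cells. Collagen made by the tumour cells could raise such a count too, so that the 2 sources cannot be told apart.

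Set 9B stood apart in DID- cells. The cell cycle list mean was 1.36 there (nearest 1.05), and the squamous differentiation list mean was 1.29 (nearest 2.38). In the same sample PNLIPRP3 measured -4.42 (nearest -1.88), STEAP4 -3.16 (nearest -1.65), CNFN -0.27 (nearest 1.05), A2ML1 -4.45 (nearest -3.06) and ITGB1 4.03 (nearest 3.25). In DID- cells of set 10A, PIGR measured -1.69 (nearest -6.28), MSMB 1.45 (nearest -1.94), LCN2 4.16 (nearest 1.6), ID1 2.63 (nearest 2.22) and COL13A1 -4.5 (nearest -3.53).

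In DID+ cells, COL13A1 measured -5.19 (nearest -4.19) and ZNF22 -5.84 (nearest -3.87) in set 10A. NTS measured 0.61 (nearest 1.69) and TGM1 -1.69 (nearest -0.82) in set 9B, and HES5 2.21 (nearest 1.79) in set 8B. In CD44n cells of set 10A, APOBEC3A measured -1.71 (nearest -2.3), MELK -2.66 (nearest -2.34), THEM5 -1.07 (nearest -0.28) and ASPM -3.73 (nearest -2.53). In CD44n cells of set 9B, TRAF5 measured -2.02 (nearest -4.08), DKK3 0.77 (nearest 0.22), KLF6 4.49 (nearest 3.76) and PDPN 2.81 (nearest 2.31).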

How the results depend on the processing

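Every alternative below was planned. For DID+ against DID-, DID+ against CD44n and DID- against CD44n in this order, the counts of 488, 0 and 928 genes became 1356, 4 and 1792 with normexp background correction, 1237, 3 and 1674 with the authors' processed values, and 1622, 3 and 1740 with array weights. They became 1139, 1 and 1635 with probes above background in all 12 samples, and 3, 0 and 76 without the filter on dim probes. Without the replicate block they were 5, 0 and 27, with only the 2 compared populations in the fit 0, 0 and 5, within slide 1 alone 2, 3 and 2, and within slide 2 alone 0, 0 and 0. Median centring gave 1327 genes for DID+ against DID-, of which 17.2% were higher against 42.4%, and the slide as a covariate gave 145. Leaving out 1 set gave from 0 (without 8A or 8B) to 4 (without 10A) genes for DID+ against DID-, 0 to 1 for DID+ against CD44n and 0 to 6 (without 9B) for DID- against CD44n. Leaving out a set, a population or the other slide leaves fewer samples, and the filters change which genes are tested; for the other settings the cause was not tested. Of the 488 genes all, and of the 928 all, kept their sign wherever they were tested, except 1 gene each with the mean of a gene's probes. For the fits without 1 set or without the block this was fixed by their same direction in 4 of 4 sets. The lists past the threshold (15, 9 and 12) were 0, 0 and 0 with an estimated correlation. Within slide 1 the list count for DID+ against DID- was 8, and within slide 2 it was 9, and 4 for DID+ against CD44n. The cell cycle list and the squamous differentiation list passed for DID+ against DID- in all 19 settings with the preset correlation. The ribosomal protein list for DID+ against CD44n turned to 0.0067 with the authors' processed values and to 0.0107 with quantile normalization, and fatty acid and cholesterol synthesis for DID+ against DID- turned to 0.0682 within slide 1. The epithelial to mesenchymal mean for DID+ against DID- changed sign, from -0.0947 to 0.1065, without the filter on dim probes. As the direction of camera's test stayed the same, it does not count as turned. The cause was not tested. Of the list values 367 of 420, 377 of 420 and 394 of 420 stayed on their side of the threshold and did not turn. Of those of named genes, 1441 of 1962, 1763 of 1776 and 1450 of 2034 did so, and 0 turned. A value that passed in neither fit could change sign and still count here. CD44, for DID+ against DID-, kept its sign in 11 of 19 settings. Signal over background limits COL1A2 and other dim genes to bounds.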

Other observations

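The tests of slides, of fibroblast RNA and of CD44 gates were chosen after the result was seen. The bound of the test of signal strength, and the reading of the splits where the real count was 0, were changed after values had been seen. The test of precision was not.

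Some transcripts of the extracellular matrix that the filter on dim probes left out were well above background only in DID+ cells. COL3A1 was at least 3.53-fold and COL6A3 at least 2.08-fold higher in DID+ than in DID- cells, each well above background in 3 of the 12 samples, the DID+ cells of sets 8A, 8B and 9B. POSTN (at least 2.20-fold) and SPARC (at least 1.65-fold), chosen after their values were seen, showed the same 3 samples. DCN (log2 difference 0.61), COL5A1 (0.10) and C1R (-0.29) of the same cell type were well above background in all 12 samples. In the fit without that filter none of the 4 passed (adjusted p = 0.136 for COL3A1 and SPARC, 0.134 for COL6A3 and 0.157 for POSTN).

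The count of 488 genes between DID+ and DID- was reached by 1 of the 35 splits of the 8 samples, the real one, and the highest other split gave 1 gene. For DID- against CD44n the 928 genes were reached by 1 of 35 splits, the real one, and the highest other gave 0. For DID+ against CD44n all 35 splits reach the real count of 0 whatever the samples show, and the highest other gave 1, so this count of splits says nothing. The 3 populations were sorted from each set, and only 8 of the 35 splits part every set as the real one does, too few for a share under 0.05. Among these 8 the highest other gave 0 in each comparison; the other 27 leave at least 1 set undivided.

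DID+ cells had a lower cell cycle list and a higher squamous differentiation list than DID- cells. The slides as the whole source are argued against, since the weaker slide still gave -0.5169 and 0.5989. So is signal strength, since the central 95% of random lists of like signal strength ended at -0.0906 and 0.0857, against -0.713 and 0.7778 (both adjusted p = 0.105 with an estimated correlation). Dilution of tumour RNA by fibroblast RNA would lower basal epithelial genes too, and their list mean of -0.2838 (SD 0.1478) neither reached 0.5 times the cell cycle shift nor stayed clear of that by its SD, so that by this rule dilution stays open for the cell cycle shift. As the whole source of both shifts dilution is argued against. It would lower squamous differentiation genes too, and their list was higher in 4 of 4 sets (0.7778, SD 0.5476), with 40 of 43 genes positive. No biological explanation was tested.

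No gene passed between DID+ and CD44n cells, while both differed from DID- cells. Beside set 8B, slide 2 held DID- cells of sets 8A and 9B, DID+ cells of set 10A and CD44n cells of set 9B. With the slide as a covariate the counts were 145 for DID+ against DID-, 0 for DID+ against CD44n and 629 for DID- against CD44n. Whether the slides add to this pattern was not tested further. Lower precision is argued against by the median SD over sets of a within-set difference. It was 0.2977 for DID+ against CD44n, 0.3069 for DID+ against DID- and 0.3122 for DID- against CD44n. The model itself gives a gene the same standard error in all 3 comparisons (median 0.16), so that the precision of its tests could not differ between them. Overlapping CD44 gates may be a source, but the CD44 transcript differed by 0.1082 (SE 0.1295) between DID+ and CD44n, and as the sort was on the protein the 2 explanations, overlapping gates and populations with like transcripts, cannot be told apart. The labels also leave open how the third population was gated.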
